A study of Mus musculus with 9 samples.

How the data were processed

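Total RNA of mouse germline stem (GS) cells and embryonic stem (ES) cells was profiled on 9 one-colour Agilent arrays, 1 array per sample. The labels put the samples in 3 groups of 3: wildtype GS, Xist knockout (KO) GS and wildtype ES cells. Per the labels, the cells were collected with trypsin, RNA was isolated with Trizol and a column, and cRNA was labelled with Cy3.

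The deposited scanner values are spot intensity values from Agilent Feature Extraction 11.0.1.1, per the file headers, with 1 set per array and no normalization between arrays. The processed signal is the spot brightness after background subtraction and detrending, per the file headers. The authors also deposited a table of processed intensity values for the same arrays. Its column medians lay between 83.3 and 83.6, its scale was linear, and its log2 values correlated with the scanner's log2 processed signal at r = 0.9948 to 0.9995 across probes. The method behind that table is not given in the sources used here. Near-equal medians are what a normalization between arrays would give, but which one was used is not known. The array design was made on the mm9 build, per the file headers. No aligner applies to arrays, and no coordinates are printed.

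From the deposited intensity values, log2 of the processed signal minus the 75th percentile of each array was computed. Each array held 43020 spots other than controls. Between 157 and 327 of them per array carried an outlier flag and were left out, and 0 spots were saturated. Spots of the same probe were averaged, which gave 39429 probes. The accession of 26055 probes matched a RefSeq gene table of the GRCm38.p6 assembly, which was used for symbols and chromosomes only, and other probes kept the name in the array file. A probe was kept if it was well above background on every measured array of at least 1 group, which left 25667 probes. A gene with several kept probes was represented by the probe with the highest mean over the arrays. This gave 21042 features, of which 14572 had a gene symbol and 6470 did not. Of the 3629 genes with over 1 probe compared, 234 had probes called in opposite directions between ES and wildtype GS cells and 226 between ES and Xist KO GS cells.

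Differences were tested with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with lmFit and eBayes on all 9 arrays, 6 residual and 2.21 prior degrees of freedom, and two-sided tests. P-values were adjusted by Benjamini-Hochberg over the features tested, and a feature was called at an adjusted p under 0.05. Where no probe of a gene was well above background on any array of a group, its fold is a bound. The mean of the brighter group was set against the mean of, per array, the higher of the gene's own level and the lowest signal among probes well above background. Such folds are written as "at least". The bound was all that could be given for 1447 of the genes called between ES and wildtype GS cells and for 1429 of those between ES and Xist KO GS cells. Apart from these bounds, differences between groups were computed within the same probe or probes.

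Gene lists were tested with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 27 lists and 3 comparisons, a family of 81 tests. Camera compares a list with the other genes. Fry, run as an alternative, tests whether a list's genes move one way on balance. The test of X-linked against autosomal genes used camera on the same fit. Its unadjusted p is not printed. The adjusted p given for the X chromosome is that of camera on each chromosome against the other genes, adjusted by Benjamini-Hochberg over the chromosomes of a comparison. The groups, the tests, the lists, the rule for named genes and all alternatives but the comparisons within a slide were chosen before the data were examined. The rule named Xist, then for each comparison the 12 genes with the largest increase and the 12 with the largest decrease. These had to be called, with groups that did not overlap, and well above background on all 3 arrays of the higher group, and names that are clone, model or accession identifiers were left out. Not every gene the rule named is reported. It also named up to 4 called members per list and comparison, and all members of 7 lists: the X-inactivation centre, spermatogonial stem cell self-renewal, naive pluripotency, both imprinted lists, meiosis and Y-linked genes. The other lists covered Xist RNA partners, differentiating spermatogonia, germ cell identity and the piRNA pathway, spermatids, primed pluripotency, DNA methylation, Polycomb complexes, Rhox and other X-linked germ cell genes, ERK and GDNF/FGF targets, p53 targets, G2 and M phase, interferon, stress response, glycolysis, cholesterol synthesis, and markers of fibroblasts, Sertoli, Leydig, macrophage and blood, and endothelial cells.

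The alternatives were quantile, median and normexp normalization, the authors' table, no filter or a stricter filter on dim probes, other rules for the probe of a gene, a fit of only the groups compared, eBayes with trend and robust, and the replicate number as a block. Further alternatives were the slide as a fixed or random block, each array left out, an estimated inter-gene correlation, fry, a 2-fold threshold, and autosomal genes matched on level. The array files held no mean spot signal, so normexp with an offset of 50 ran on the median spot and background signals, a change made after the files were seen. Quantile normalization followed, so this alternative changed the signal, the background correction and the scaling together. The normalization alternatives kept the same probe for each gene. The arrays lay on 3 slides, each scanned as 1 batch. The wildtype GS arrays and Xist KO GS replicate 1 shared slide 1. Xist KO GS replicates 2 and 3 and ES replicates 1 and 2 shared slide 2, and ES replicate 3 lay alone on slide 3. Between the GS groups the fixed slide block therefore compares Xist KO GS replicate 1 alone with the wildtype arrays. With that replicate left out, group and slide coincide between the GS groups.

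The scripts' steps were tested on simulated data made from the Xist KO and wildtype GS comparison, with 200 of 21042 genes changed in each of 20 runs. limma recovered 9.3% of genes changed by 0.5 on the log2 scale, 66.0% of those changed by 1, 92.6% of those changed by 2 and 99.5% of those changed by 4, with 7.3 false calls per run. Camera found a list of 22 genes shifted by -0.3 in 20 of 20 runs and an unchanged list in 0 of 20. The simulated noise was independent between genes, while the estimated correlation of the fibroblast list was 0.166. These runs therefore do not test the preset correlation of 0.01 on real lists. The limma rates hold for 200 changed genes, where the adjustment is less strict than with few. The number of arrays limits the precision, and the median SE of a log2 difference was 0.15. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.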

Results

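Gene expression was measured in cultured mouse GS cells, which are spermatogonial stem cells grown from the postnatal testis, and in ES cells, the pluripotent cells of the early embryo. A wildtype GS line, an Xist KO GS line and a wildtype ES line were each measured in 3 samples, on 9 arrays in all. The labels give a DBA/2 background for both GS groups and a C57BL/6 background for the ES cells, so cell type and strain differ together wherever ES cells are compared. The share of probes well above background ran from 52.3% on the array of ES replicate 1 to 73.1% on that of Xist KO GS replicate 1. The labels call the samples independent without saying that they were separate cultures, so the p-values measure only the spread between these samples. The labels name 1 line per group, so a difference between groups is also a difference between those lines.

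Xist, the non-coding RNA that coats and silences the inactive X chromosome in female cells, was not well above background on any array of any group. With probe A_52_P113537 the normalised log2 level was -7.12 ± 0.57 in wildtype GS, -7.72 ± 0.50 in Xist KO GS and -6.94 ± 0.55 in ES cells (mean ± SD, n = 3). With probe A_52_P300376 it was -5.66 ± 0.44, -6.74 ± 0.97 and -6.53 ± 0.50 in the same order. On single arrays the first probe ran from -8.20 in Xist KO GS replicate 1 to -6.31 in ES replicate 1, and the second from -7.57 in Xist KO GS replicate 2 to -5.24 in wildtype GS replicate 1. No fold was computed, and these levels neither bear out nor contradict the genotype labels. The labels do not say which part of the gene was deleted, and no probe was matched to its antisense partner Tsix.

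The main comparison asked how the loss of Xist changes gene expression in GS cells. Few genes were called. Saa3, which encodes an acute-phase serum amyloid A protein, fell 4.28-fold in Xist KO GS cells, from a normalised log2 level of -0.87 ± 0.42 to -2.96 ± 0.14 (SD, n = 3; log2 difference -2.10, SE 0.22, adjusted p = 0.0425). Cebpd, a transcription factor of the acute-phase and inflammatory response, fell 1.92-fold, from 0.24 ± 0.08 to -0.70 ± 0.04 (SD, n = 3; log2 difference -0.94, SE 0.085, adjusted p = 0.0165). The features XM_001471788, NM_133362 and BX529057, which had no gene symbol here and are named after their values were seen, rose 12.8-fold, 12.2-fold and 6.40-fold (log2 differences 3.67, 3.61 and 2.68). Their adjusted p-values were 4.82e-07, 1.94e-06 and 0.000388. BX529057 lay near background in wildtype GS replicates 1, 2 and 3, at -5.06, -5.52 and -5.17. The lowest signals among probes well above background on these arrays were -5.01, -5.42 and -6.03, so its fold is uncertain. In each of these 5 features every Xist KO array lay beyond every wildtype array, as the plot of called features shows.

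Among the 21042 features tested with limma, 5 were called, 3 higher and 2 lower, and 4 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 2651 features, 1964 higher and 687 lower, against 1052 expected by chance. The median of all features was 0.065 and depended on the scaling. It was 0.005 with the authors' values, 0.019 with normexp and quantile normalization, 0.027 with quantile normalization and 0.088 with median scaling. The unadjusted counts were not made under another scaling or with the slide as a block. Xist KO GS replicates 2 and 3 lay on a slide without wildtype arrays. How far the excess over chance, and that of higher features, depends on scaling or slide is therefore not known. With the slide as a fixed block 3 were called, and of the 5 only XM_001471788 and NM_133362 kept their call, while BX529057, Cebpd and Saa3 lost it (adjusted p = 0.0525, 0.391 and 0.524). Their differences stayed about as large, at 2.78 (SE 0.219), -0.89 (SE 0.133) and -2.07 (SE 0.341). The SEs grew from 0.145, 0.085 and 0.22, with 1 Xist KO array left on the wildtype slide. The block also left fewer residual degrees of freedom, and the parts of the 2 in the lost calls were not separated. Within slide 1, where only Xist KO GS replicate 1 met the wildtype arrays, XM_001471788 and NM_133362 were called, and with the slide as a random block all 5 were. Normexp on the median signals followed by quantile normalization, which changed several choices together, gave smaller differences for BX529057 (1.04) and Saa3 (-1.42). Without Xist KO GS replicate 1 the count was 18, but group and slide then coincide. These calls therefore cannot be told apart from a difference between slides. Without wildtype GS replicate 1, wildtype GS replicate 2 or Xist KO GS replicate 2 the count was 3. Over the alternatives Saa3 was called in 8 of 22 and Cebpd in 12 of 23. Saa3 lost its call with any single array left out (adjusted p = 0.0583 to 0.184 by limma). Its difference stayed between -2.25 and -1.86 in these fits. Under median scaling 75% of the called features were higher, against 60%, because Cebpd lost its call (adjusted p = 0.159 by limma). The features called higher were the same, so this is no change of direction.

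**Figure D1:**
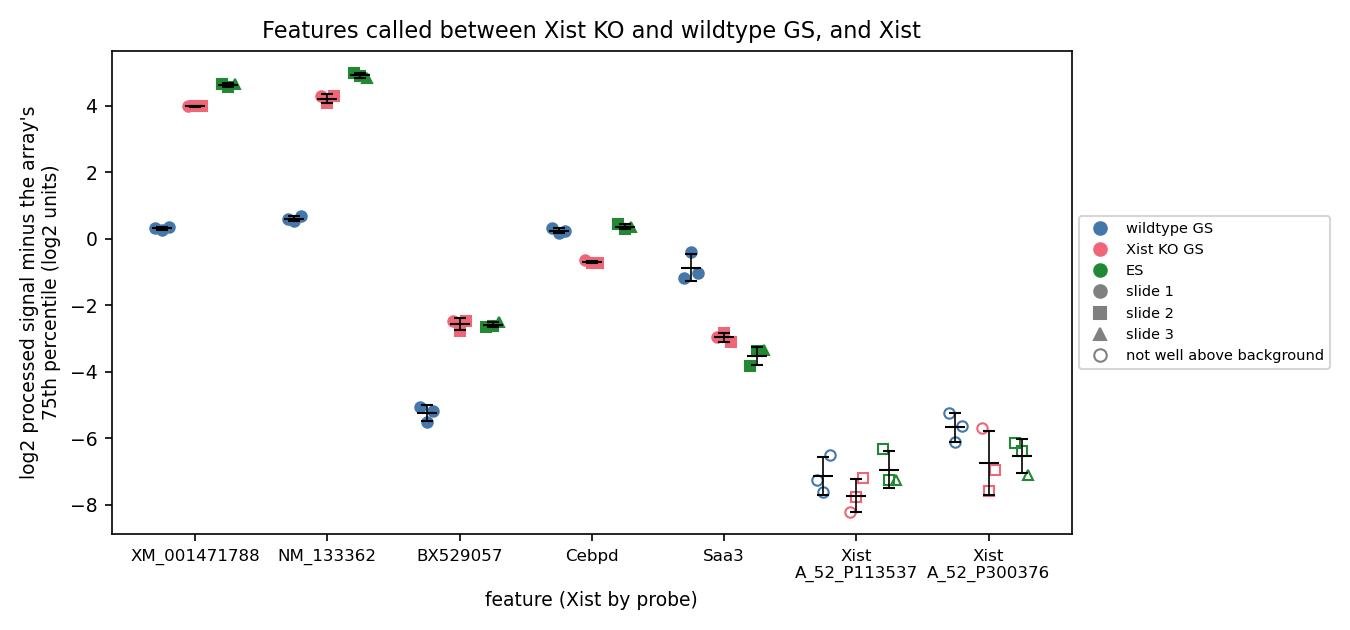
Normalised log2 signal (log2 units above or below the array's 75th percentile) of the 5 features called between Xist KO and wildtype GS cells and of the Xist probes, with 1 point per array, coloured by group and shaped by slide, and bars for the mean and SD of 3 arrays. Xist KO arrays lie 3.67, 3.61 and 2.68 above wildtype on average in the features that rose, and open Xist points mark arrays where the probe was not well above background.

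Because Xist acts on the X chromosome, X-linked genes were set against autosomal genes. Xist was not well above background in wildtype GS cells, and 12 Y-linked probes were on all arrays of both GS groups. A missing shift here therefore cannot show what the loss of Xist does in cells that express it. The 545 X-linked genes had a median log2 difference of 0.037 between Xist KO and wildtype GS cells, which was -0.024 relative to the 14017 autosomal genes (adjusted p = 0.626 by camera, adjusted over chromosomes). No gene placed on the X chromosome was called by limma, and at an unadjusted p under 0.05 25 X-linked genes were lower and 45 higher. The called features XM_001471788, NM_133362 and BX529057 had no chromosome here, so they counted neither as X-linked nor as autosomal. The shift was -0.026 with the slide as a block and -0.027 within slide 1, both resting on Xist KO GS replicate 1, and passed in neither. No chromosome passed adjustment over chromosomes, the lowest adjusted p being 0.474 for chromosome 3. Of the X-inactivation centre list, 4 of 11 genes were tested and 0 were called, with 1 lower at an unadjusted p under 0.05. The ubiquitin ligase gene Rlim, an activator of Xist in female cells, differed by -0.03 (SE 0.12, adjusted p = 0.933), and the non-coding Ftx by 0.33 (SE 0.29, adjusted p = 0.636). The list's median was 0.007 (adjusted p = 0.444). Without a filter on dim probes it was -0.11 and passed camera (adjusted p = 0.0331). The 16 Xist RNA partners and X-silencing factors, Smchd1 among them with a difference of 0.01, had a median of 0.008 (adjusted p = 0.508) and 0 called members.

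Markers of fibroblasts were lower as a group in Xist KO GS cells. Of 22 tested markers 21 had a negative difference, with a median of -0.307 (adjusted p = 6.88e-10). The adjusted p = 0.095 with an estimated correlation, so the list's call was lost there, and it was 0.0134 by fry. No member passed over all genes, with 9 lower at an unadjusted p under 0.05. With p-values adjusted over the list alone, 3 were lower: the smooth muscle actin Acta2 (-0.71, SE 0.155), the collagen cross-linking enzyme Lox (-0.53, SE 0.128) and the matrix protein Fbln2 (-0.48, SE 0.112), each at 0.0237. Within slide 1 the median was -0.291 (adjusted p = 3.81e-08). It was the same with the slide as a fixed block (adjusted p = 8.82e-09), because both rest on 1 Xist KO sample, replicate 1.

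Smaller shifts of other lists passed camera in the same comparison, all with 0 members called over all genes. ERK and GDNF/FGF target genes had a median of -0.114 (adjusted p = 0.00481, and adjusted p = 0.22 with an estimated correlation). Its members Myc, at -1.43 (SE 0.482), and Etv1, at -0.83 (SE 0.343), did not pass, and 4 of 20 were lower at an unadjusted p under 0.05. Genes of G2 and M phase had a median of -0.101 (adjusted p = 0.00481, and adjusted p = 0.189 with an estimated correlation), with 1 of 20 lower at an unadjusted p under 0.05. p53 target genes had a median of -0.082 (adjusted p = 0.0146, and adjusted p = 0.45 with an estimated correlation), with 4 of 18 lower at an unadjusted p under 0.05, among them the death receptor Fas at -0.61 (SE 0.109). Cholesterol synthesis genes had a median of 0.163 (adjusted p = 0.0191, and adjusted p = 0.165 with an estimated correlation), with 5 of 20 higher at an unadjusted p under 0.05. Dhcr7, the last enzyme of the pathway, was at 0.40 (SE 0.132, adjusted p = 0.337). With the slide as a block the medians were -0.063 for ERK and GDNF/FGF targets (adjusted p = 0.0206), -0.145 for p53 targets (0.00129), 0.18 for cholesterol synthesis (0.0112) and -0.032 for G2 and M genes (0.0511). Fibroblast markers were lower in the same samples (median -0.307), and without Xist KO GS replicate 1 only 3 of the 6 lists that passed camera were called. The p53 target median depended on single samples: it was -0.019 without Xist KO GS replicate 1 (adjusted p = 0.118), -0.037 without replicate 2 (adjusted p = 0.0873) and -0.151 without replicate 3, whose own median of 0.075 lay above every wildtype array. Over all alternatives the medians ran from -0.172 to -0.063 for ERK and GDNF/FGF targets, from -0.183 to -0.032 for G2 and M genes and from 0.075 to 0.229 for cholesterol synthesis, with calls in 21, 20 and 19 of 24. By fry the cholesterol list kept its call (adjusted p = 0.00102), and ERK and GDNF/FGF targets (0.0966), G2 and M genes (0.0966) and p53 targets (0.222) lost it.

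Maternally expressed imprinted genes had a median of -0.122 (adjusted p = 0.0316, and adjusted p = 0.211 with an estimated correlation), with 0 of 16 called and 2 higher and 2 lower adjusted over the list alone. The member with the largest difference was Dcn, a matrix proteoglycan also made in quantity by fibroblasts, at -1.34 (SE 0.241, adjusted p = 0.201), while the placental growth regulator Phlda2 was at 0.84 (SE 0.195, adjusted p = 0.257). With the slide as a block the median was -0.105 (adjusted p = 0.00859). The call was kept in 18 of 24 alternatives (medians -0.152 to -0.08), and lost by fry (adjusted p = 0.101), with median scaling (0.0744), with no filter (0.102), without Xist KO GS replicate 1 (0.155) and without replicate 2 (0.0596). Paternally expressed imprinted genes had a median of -0.075 (adjusted p = 0.229), with 0 of 22 called and 3 higher and 2 lower adjusted over the list alone.

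No gene that marks GS cells themselves was called. Spermatogonial stem cell self-renewal genes had a median of 0.073 (adjusted p = 0.955), with 0 of 28 called, and 1 higher adjusted over the list alone. The GDNF receptor genes Ret and Gfra1 differed by -0.02 (SE 0.442) and -0.30 (SE 0.391), and the stem cell factor Zbtb16 by -0.07 (SE 0.10). Differentiating spermatogonia genes had a median of 0.197 (adjusted p = 0.152 by camera, 0.0324 by fry), with 3 higher and 1 lower adjusted over the list alone, and the receptor gene Kit was at 0.39 (SE 0.08, adjusted p = 0.243). Germ cell identity and piRNA genes had a median of 0.128 (adjusted p = 0.307 by camera, 0.0215 by fry). Naive pluripotency genes had a median of 0.049 (adjusted p = 0.229), with 2 lower adjusted over the list alone and the bone matrix protein Spp1 at -1.09 (SE 0.172, adjusted p = 0.185). Their median turned to -0.042 with the slide as a fixed block and within slide 1. Both are the same comparison of 1 Xist KO array, replicate 1, with the wildtype arrays. The medians were -0.055 for meiosis genes (adjusted p = 0.229), 0.11 for spermatid genes (adjusted p = 0.955), 0.059 for Rhox and other X-linked germ cell genes (adjusted p = 0.837) and -0.255 for Y-linked genes (adjusted p = 0.229), with 0 members called in each.

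ES cells were compared with wildtype GS cells, a comparison of a pluripotent with a germline stem cell. Pluripotency genes rose and germ cell genes fell in ES cells. Fgf4, a growth factor of pluripotent cells, was at least 2177-fold higher (log2 levels 5.60 ± 0.14 against -7.08 ± 0.49, SD, n = 3), and the nuclear receptor gene Nr0b1 at least 342-fold higher. Nanos2, an RNA-binding protein that keeps spermatogonial stem cells undifferentiated, was at least 155-fold lower (-6.48 ± 0.75 against 2.48 ± 0.09, SD, n = 3), and the GDNF receptor Ret at least 75.7-fold lower. The adjusted p-values were 8.88e-09, 1.18e-08, 4.88e-08 and 6.2e-07.

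With limma, 16058 of 21042 features were called between ES and wildtype GS cells, 8354 higher and 7704 lower in ES cells, and 10383 at 2-fold or more. Strain and cell type cannot be separated in these counts. No slide held arrays of both groups, and with the slide as a fixed block, which links them only through Xist KO GS arrays, 12420 were called. The direction of the majority depended on the scaling: 52.0% of calls were higher in ES cells, against 60.5% with median scaling and 48.2% with quantile normalization. Median scaling moved the median of all genes from 0.075 to 0.353. The brightest 1% of probes started at 7.49 in ES against 6.36 in wildtype GS cells. Bright genes with small differences may therefore depend on the normalization, which was not tested by brightness.

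Naive pluripotency genes stood at a median of 4.21 (adjusted p = 1.05e-09, and adjusted p = 0.0324 with an estimated correlation), with 28 of 29 higher in ES cells and 1 lower, the same counts as adjusted over the list alone. The TGF-beta family ligand Gdf3 rose by 7.71 (SE 0.089), the core factors Pou5f1 by 5.95 (SE 0.214) and Sox2 by 4.21 (SE 0.089), and Esrrb by 4.65 (SE 0.12). The exception was the only kept probe of the homeobox gene Nanog, lower by a log2 difference of -0.53 (SE 0.12, adjusted p = 0.00361). Whether this probe measures Nanog alone is not known, so its value is uncertain as that of the gene. The list's median was 4.07 with the slide as a block (adjusted p = 5.93e-10).

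Germ cell identity and piRNA pathway genes were all lower in ES cells, 23 of 23, with a median of -4.68 (adjusted p = 9.11e-10, and adjusted p = 0.0139 with an estimated correlation). The RNA export gene Nxf2 differed by -7.38 (SE 0.115), the small RNA methyltransferase gene Henmt1 by -6.55 (SE 0.303), and the surface protein gene Tex101 by -6.52 (SE 0.166). The piRNA factor gene Asz1 was at least 40.5-fold lower, and Tdrd1, another gene of that pathway, at least 21.96-fold lower.

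Spermatogonial stem cell self-renewal genes had a median of -2.29 (adjusted p = 0.00987, and adjusted p = 0.202 with an estimated correlation), with 18 of 28 lower and 6 higher. Lower members were Zbtb16 (-8.12, SE 0.089), the immediate-early factor Egr2 (at least 43.0-fold), Gfra1 (at least 13.1-fold) and the inhibitor of differentiation Id4 (-4.93, SE 0.119). The higher members include genes that ES cells are known to use: the adhesion molecule Cdh1 (6.89, SE 0.119), the chromatin factor Utf1 (6.09, SE 0.091) and Etv5 (1.71, SE 0.144). Cd9 was higher by 0.40 and turned to -0.298, -0.402 and -0.294 with quantile normalization, normexp followed by quantile normalization, and the authors' values.

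Meiosis genes had a median of -1.38 (adjusted p = 0.00452, and adjusted p = 0.095 with an estimated correlation), with 18 of 26 lower and 3 higher, and 19 lower adjusted over the list alone. The synaptonemal complex genes Sycp1 and Sycp3 differed by -5.64 (SE 0.451) and -4.38 (SE 0.138), the meiotic cohesin gene Smc1b by -5.41 (SE 0.178), and Majin, a gene of telomere attachment in meiosis, by 2.84 (SE 0.13). Rhox and other X-linked germ cell genes had a median of -2.37 (adjusted p = 0.00481, and adjusted p = 0.095 with an estimated correlation), with 16 of 23 lower and 4 higher. Tex13b was at least 209-fold lower, Tktl1 differed by -6.25 (SE 0.192), and the homeobox gene Rhox5 by 9.40 (SE 0.171), although near-identical copies make single Rhox genes uncertain. Differentiating spermatogonia genes went both ways, 7 of 14 higher and 6 lower (median 0.312, adjusted p = 0.781), with the transcription factor Sohlh1 at -8.98 (SE 0.198) and Kit at 2.47 (SE 0.08). Spermatid genes had a median of -0.657 (adjusted p = 0.229), with 8 of 13 lower and 3 higher.

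Y-linked genes were lower in ES cells, 7 of 7, with a median of -5.45 (adjusted p = 0.00236, and adjusted p = 0.412 with an estimated correlation). The translation factor gene Eif2s3y was at least 34.0-fold lower, Usp9y at least 14.0-fold, the helicase gene Ddx3y at least 9.96-fold and Zfy2 at least 11.4-fold. Of 32 probes of Y-linked genes, 12 were well above background on all 3 arrays of each GS group and 0 on all 3 ES arrays. On no ES array were 26, but 16 were also on no array of each GS group. Of the 12 bright in GS cells, 10 were well above background on no ES array. Rbmy, a multi-copy family whose members share sequence, differed by -9.24 (SE 0.567) and is uncertain.

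Genes of G2 and M phase were higher in ES cells, 17 of 20, with 1 lower and a median of 1.95 (adjusted p = 0.000238, and adjusted p = 0.095 with an estimated correlation). The mitotic kinase gene Plk1 rose by 3.98 (SE 0.118) and the mitotic ubiquitin enzyme Ube2c by 3.72 (SE 0.09). Stress response genes were higher in 14 of 19 and lower in 2 (median 2.42, adjusted p = 0.00236, and adjusted p = 0.211 with an estimated correlation). Among them the glutathione-degrading enzyme Chac1 rose by 6.72 (SE 0.151), the oxidoreductase Nqo1 by 4.88 (SE 0.105) and asparagine synthetase, Asns, by 4.62 (SE 0.125). Glycolysis genes were higher in 13 of 19 and lower in 2 (median 2.01, adjusted p = 0.0047, and adjusted p = 0.569 with an estimated correlation), including the hexokinase Hk2 (5.68, SE 0.129) and Pgk1 (3.71, SE 0.091).

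**Figure D2:**
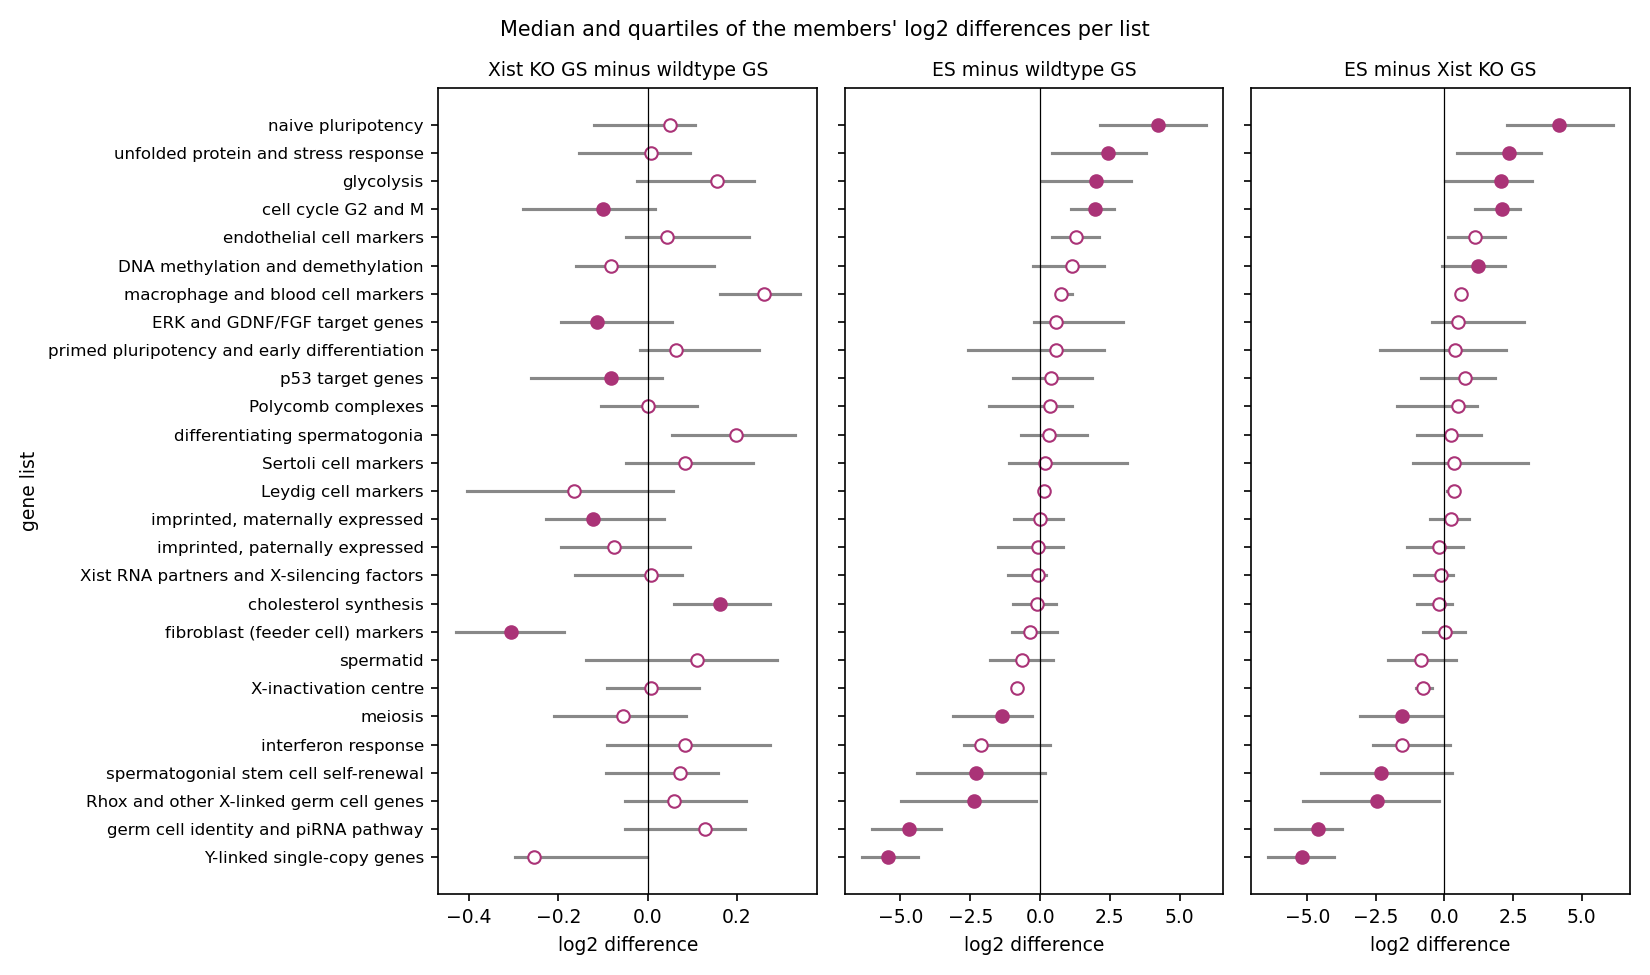
Median (points) and quartiles (bars) of the members' log2 differences for each preset list in the 3 comparisons, with filled points where camera's adjusted p was under 0.05 and a separate log2 axis for each comparison. In ES against wildtype GS cells naive pluripotency lies at 4.21 and germ cell identity at -4.68, while the lists between the GS groups lie close to 0, with fibroblast markers at -0.307.

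Other genes with large differences were calcitonin, Calca (at least 269.8-fold higher in ES cells), the transglutaminase Tgm1 (at least 375-fold), Fam25c (at least 321-fold), the junctional adhesion molecule Jam2 (at least 419-fold) and Gtsf1l (at least 417-fold). In the other direction were Asb9 (at least 381-fold lower), alpha-fetoprotein, Afp (at least 159.6-fold), the endoderm factor Foxa2 (at least 121-fold), Clic6 (at least 145.5-fold) and the homeobox gene Hoxb8 (at least 112-fold). Liver glycogen phosphorylase, Pygl, differed by -9.72 (SE 0.097), with 2 of 3 ES arrays well above background. Zic1 was lower with its brightest probe, which was not well above background on any ES array, but higher by 1.22 with its other probe, which was well above background on all 9 arrays, so its direction is uncertain.

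**Figure D3:**
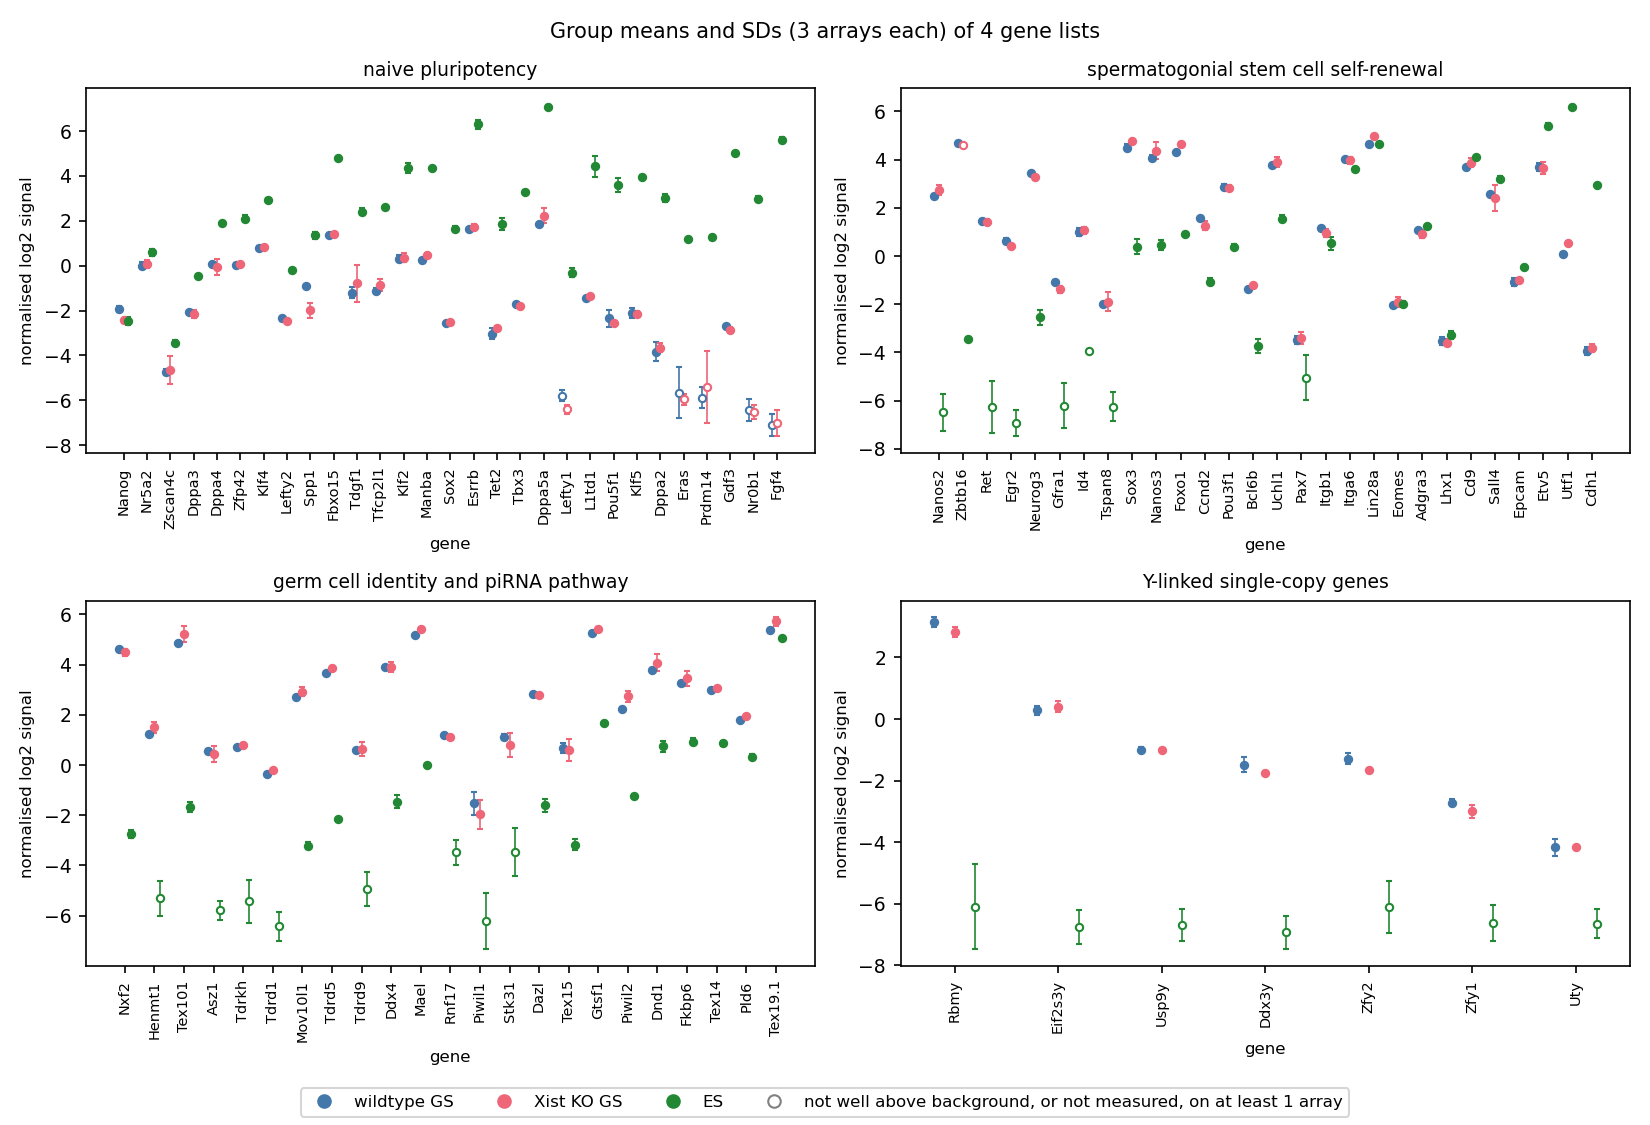
Normalised log2 signal (group mean with SD of 3 arrays) of the tested members of 4 gene lists, ordered by the difference between ES and wildtype GS cells, with open points where a probe was not well above background, or not measured, on at least 1 array. The GS groups lie close together in each list, and 28 of 29 naive pluripotency genes are higher and 23 of 23 germ cell genes lower in ES than in wildtype GS cells.

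X-linked genes had a median log2 difference of -0.342 between ES and wildtype GS cells, -0.382 relative to autosomal genes (adjusted p = 0.85 by camera, adjusted over chromosomes). Of the X-linked genes 36.5% were called higher and 47.9% lower, against 40.4% and 38.6% of autosomal genes. Rlim differed by -1.01 (SE 0.12), and 3 of 4 X-inactivation centre genes were lower (median -0.843, adjusted p = 0.266). Of the Xist RNA partners, 3 of 16 were higher and 7 lower (median -0.074, adjusted p = 0.746), with Smchd1, a chromatin protein of the inactive X, at -2.42 (SE 0.21).

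ES cells were also compared with Xist KO GS cells, which shares the ES arrays with the comparison to wildtype GS cells and is not independent of it. Pluripotency genes were higher and germ cell genes lower: Fgf4 was at least 2224-fold higher, Nr0b1 at least 364-fold higher, Nanos2 at least 186-fold lower and Ret at least 74.6-fold lower in ES cells. limma called 15636 features, 7820 higher and 7816 lower, and 9983 at 2-fold or more. With the slide as a block 14940 were called, and within slide 2, which held Xist KO GS replicates 2 and 3 and ES replicates 1 and 2, 12918 were called. With median scaling, which moved the median of all genes from 0.05 to 0.304, 58.9% of calls were higher in ES cells, and with quantile normalization 47.4%.

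Naive pluripotency genes were higher in 28 of 29 and lower in 0 (median 4.17, adjusted p = 5.05e-10, and adjusted p = 0.0324 with an estimated correlation). Gdf3 rose by 7.86 (SE 0.089) and Pou5f1 by 6.15 (SE 0.214), while the Nanog probe was at -0.03 (SE 0.12, adjusted p = 0.825). Germ cell identity and piRNA genes were lower in 23 of 23 (median -4.61, adjusted p = 9.11e-10, and adjusted p = 0.0139 with an estimated correlation). Spermatogonial stem cell self-renewal genes were lower in 19 of 28 and higher in 6 (median -2.33, adjusted p = 0.00987, and adjusted p = 0.202 with an estimated correlation), with Zbtb16 at -8.04 (SE 0.10) and Cdh1 at 6.77 (SE 0.119). Meiosis genes were lower in 18 of 26 and higher in 4 (median -1.55, adjusted p = 0.00691, and adjusted p = 0.095 with an estimated correlation). Rhox and other X-linked germ cell genes were lower in 17 of 23 and higher in 4 (median -2.46, adjusted p = 0.00634, and adjusted p = 0.095 with an estimated correlation). Y-linked genes were lower in 7 of 7 (median -5.19, adjusted p = 0.00255, and adjusted p = 0.415 with an estimated correlation).

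G2 and M genes were higher in 17 of 20 and lower in 1 (median 2.10, adjusted p = 4.2e-05, and adjusted p = 0.095 with an estimated correlation). Stress response genes were higher in 14 of 19 and lower in 3 (median 2.35, adjusted p = 0.00206, and adjusted p = 0.211 with an estimated correlation), and glycolysis genes higher in 13 of 19 and lower in 2 (median 2.07, adjusted p = 0.00481, and adjusted p = 0.569 with an estimated correlation). DNA methylation and demethylation genes were higher in 13 of 20 and lower in 4 (median 1.24, adjusted p = 0.0366, and adjusted p = 0.189 with an estimated correlation), with the methyltransferase cofactor Dnmt3l at 5.57 (SE 0.11), the demethylation enzyme Tet2 at 4.60 (SE 0.165) and Mbd2 at -3.18 (SE 0.121). This last list's adjusted p was 0.0511 with the slide as a block. Among genes with large differences, Robo4, an endothelial guidance receptor, differed by 8.44 (SE 0.708, well above background on 1 of 3 Xist KO GS arrays), Etl4 at least 63.0-fold higher, the immediate-early factor Egr4 at -8.46 (SE 0.133) and Radx, a replication fork protein, at least 56.2-fold lower. X-linked genes had a median of -0.336, -0.353 relative to autosomal genes (adjusted p = 0.853 by camera, adjusted over chromosomes).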

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

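The tests within a slide were chosen after seeing the data. The shift of X-linked against autosomal genes between Xist KO and wildtype GS cells kept its sign and stayed short of the threshold under all 25 alternatives (-0.032 to -0.003). The ES counts stayed within 1.5 times except at 2-fold or more, which gave 10383 against wildtype GS and 9983 against Xist KO GS cells because the threshold is stricter. Between Xist KO and wildtype GS cells 5 features were called, and the count was 11 with quantile normalization, 28 with normexp and quantile normalization together, 11 with the authors' values, 3 without a filter on dim probes, 3 with only the groups compared, 12 with trend and robust, 3 with the replicate number as a block, 3 with the slide as a block and 2 within slide 1. At 2-fold or more the count of 4 became 7 with normexp and quantile normalization, 7 with trend and robust and 2 within slide 1. Replicates of the same number showed no pairing: their correlations ran from -0.146 to 0.042 and none was highest with its own number.

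With each array left out, the counts between Xist KO and wildtype GS cells ran from 3 to 18. Those at 2-fold or more ran from 3 to 17, and the X shift from -0.032 to -0.009. The count of 18 came without Xist KO GS replicate 1, where group and slide coincide. The ES counts ran from 15048 to 16457 against wildtype GS and from 14797 to 15892 against Xist KO GS cells. Called lists ran from 22 to 26 in all, from 3 to 7 between the GS groups, from 9 to 9 for ES against wildtype GS and from 9 to 10 for ES against Xist KO GS cells. Of 25 called lists in all, 16 were called with the stricter filter, 4 with an estimated correlation and 46 with fry. Between the GS groups 6 lists became 3 with the stricter filter and 0 with an estimated correlation. For ES against wildtype GS cells 9 became 2 with an estimated correlation and 21 with fry, and for ES against Xist KO GS cells 10 became 6 with the stricter filter, 2 with an estimated correlation and 21 with fry.

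Some genes turned direction. With quantile normalization, normexp then quantile normalization, and the authors' values, Cd9 was at -0.298, -0.402 and -0.294 for ES against wildtype GS (0.402 before) and at -0.324, -0.391 and -0.294 against Xist KO GS cells (0.245 before). In the same order Lin28a was at -0.884, -0.915 and -0.891 against wildtype GS cells (0.008 before), and Syce2 at -0.604, -0.461 and -0.615 against wildtype GS (0.157 before) and at -0.544, -0.456 and -0.521 against Xist KO GS cells (0.068 before). Against Xist KO GS cells NM_133362 was at -0.016 with quantile normalization and XM_001471788 at -0.012 with normexp then quantile normalization. With the stricter filter Zic1 was at 1.222 and 1.678, since another probe then represents it. With the mean of probes Gnas was at -0.591 and -0.187 (0.667 and 0.827 before), and with each probe on its own Zdbf2 was at 0.726 and 1.081 (-0.061 and -0.113 before). Between the GS groups the X-inactivation centre list was at -0.11 without a filter and passed camera there (adjusted p = 0.0331). The naive pluripotency list was at -0.042 with the slide as a block and within slide 1, both resting on Xist KO GS replicate 1 alone. Other than for the filters, probes and thresholds, the cause was not tested. Signal over background limits dim genes, and 15995 genes were tested with the stricter filter.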

Other observations

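The tests of slides, strain segments, feeder share, array brightness and a missing Y chromosome were chosen only after the result was seen. Imprinted genes went both ways in ES against wildtype GS cells. Of paternally expressed genes 8 of 22 were higher and 10 lower (median -0.06, adjusted p = 0.77), with Snrpn at 4.15 (SE 0.157), Mest at 2.01 (SE 0.101) and the growth factor Igf2 at -3.32 (SE 0.192). Of maternally expressed genes 6 of 16 were higher and 6 lower (median -0.015, adjusted p = 0.981), with Phlda2 at 3.34 (SE 0.195), the non-coding Meg3 at 1.73 (SE 0.105) and the cell cycle inhibitor Cdkn1c at -3.27 (SE 0.085). DNA methylation genes were higher in 13 of 20 and lower in 5 (median 1.16, adjusted p = 0.108), with Dnmt3l at 5.93 (SE 0.11) and Mbd2 at -3.17 (SE 0.121). Polycomb genes were higher in 15 of 28 and lower in 11 (median 0.353, adjusted p = 0.837), with the methyltransferase Ezh2 at 4.04 (SE 0.099) and Cbx8 at least 24.6-fold lower. Between the GS groups the DNA methylation list had a median of -0.082 (adjusted p = 0.273) and the Polycomb list of 0 (adjusted p = 0.6).

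ERK and GDNF/FGF targets in ES against wildtype GS cells were higher in 11 of 20 and lower in 4 (median 0.56, adjusted p = 0.356), with Myc at 4.59 (SE 0.482) and the immediate-early factor Egr1 at -7.18 (SE 0.15). p53 targets were higher in 9 of 18 and lower in 7 (median 0.405, adjusted p = 0.77). Interferon genes were lower in 9 of 15 and higher in 4 (median -2.12, adjusted p = 0.229), with Oasl2 at least 29.0-fold lower and the RNA sensor gene Ddx58 at 4.68 (SE 0.08). Primed pluripotency genes were higher in 6 of 12 and lower in 4 (median 0.559, adjusted p = 0.746), with Nodal at 5.74 (SE 0.204). Cholesterol synthesis genes were higher in 6 of 20 and lower in 7 (median -0.096, adjusted p = 0.77), with Ebp at 5.23 (SE 0.172) and Insig1 at -2.42 (SE 0.144). Fibroblast markers were higher in 7 of 22 and lower in 11 (median -0.37, adjusted p = 0.504), with Pdgfra at least 10.9-fold lower and Acta2 at 2.27 (SE 0.155). The Sertoli list had a median of 0.163 (adjusted p = 0.77), the Leydig list of 0.13 (0.955), the macrophage and blood list of 0.765 (0.428) and the endothelial list of 1.29 (0.376). Between the GS groups the medians were 0.064 for primed pluripotency (adjusted p = 0.77), 0.084 for interferon (0.955), 0.007 for stress response (0.446), 0.156 for glycolysis (0.444), 0.083 for Sertoli (0.916), -0.166 for Leydig (0.267), 0.26 for macrophage and blood (0.306) and 0.044 for endothelial markers (0.932), with 0 members called by limma in each. At an unadjusted p under 0.05 the interferon list had 1 lower, stress response 2 higher and 1 lower, glycolysis 2 higher, Leydig 1 lower, and primed pluripotency, Sertoli, macrophage and endothelial lists 0.

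The 6 arrays of a comparison allow 10 splits, too few for a share under 0.05. Between the GS groups the real split gave 5 called features and the highest other 0, 4 against 0 at 2-fold or more, and 6 against 3 called lists, each with 1 of 10 splits as large. The X shift was 0.024 in size against 0.034, with 3 of 10 as large. For ES against wildtype GS cells the counts were 16058 against 0, with 1 of 10 as large, and 9 against 10 lists, with 2 of 10 as large. For ES against Xist KO GS cells they were 15636 against 0 and 10 against 6 lists, each with 1 of 10 as large.

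The 3 features higher in Xist KO GS cells were set against a difference between slides. Xist KO GS replicate 1 shared slide 1 with the wildtype arrays and exceeded the highest of them by at least 2.59 in each feature. The largest SD in a group was 0.238. In this array the difference was thus present within 1 slide. The features were picked partly on its values, and only 1 Xist KO array bears on this, so a slide difference is not excluded. Against Xist KO GS cells, ES cells, which are of another strain, were higher by 0.69 in NM_133362 and 0.64 in XM_001471788. Both differences were called (adjusted p = 0.000193 and 6.68e-05 by limma), while BX529057 was alike (-0.013). Cell type differs here too, so these levels do not decide whether the Xist KO line holds genome segments of another strain. An effect of the Xist genotype stayed open and was not tested.

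Fibroblast markers were lower in Xist KO GS cells by a median of -0.307. Within slide 1 the median was -0.29, from 1 Xist KO array, which does not settle whether slides differ. A smaller share of feeder cells also stays open: that 21 of 22 markers were lower is the pattern itself and tests nothing, and the labels name no feeder cells. Saa3 lay -1.39 beyond Acta2, the marker with the lowest difference, but how much of these markers GS cells express themselves was not measured, so this decides nothing about Saa3. An effect of the Xist genotype stayed open and was not tested.

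Y-linked genes were lower in ES cells, and of 32 Y-linked probes 0 were well above background on all 3 ES arrays. On no ES array were 26, but 16 were also on no array of each GS group. Of the 12 that were bright on all GS arrays, 10 were well above background on no ES array. Of 14488 other probes within the same range of GS levels, 84.1% were well above background on all 3 ES arrays. They were not matched in level within that range. The lowest signal well above background was highest on ES replicate 1 among the ES arrays. The GS levels of the 12 bright Y-linked probes lay a median of 2.53 above it, and the dimmest at -0.009. Dimmer ES arrays thus do not account for these probes as a set, but are not excluded for the dimmest. The count of 0 is the pattern itself, so it does not test whether the ES line lacks a Y chromosome, which stays open. Strain variants under the probes were not looked at.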
